A study of Mus musculus with 6 samples.

How the data were processed

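Single-cell RNA sequencing was carried out on cells isolated from the hippocampus of 5xFAD mice, a transgenic model of amyloid deposition, on a B6/SJL background. Per the labels, the animals were 8 months old and tissue was taken 3 weeks after stereotaxic injection of LV-Control, LV-Aducanumab or LV-⍺Aβ-Gas6, and 10000 cells were targeted per library. The labels conflict on the vector: titles and treatment entries name the 3 vectors, while the protocol entry of every sample names the control vector. Groups here follow the titles. The deposited files were 6 tables of raw UMI counts per gene and cell barcode, which the authors made with Cell Ranger 5.0.0 against the mouse build mm10, per the submitters' processing notes. The same notes name Seurat, without its role. Cell filters and the gene annotation behind the counts are not given in the sources used here.

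Each group had 2 tables, called replicates 1 and 2 in the labels. The replicates of a group held the same cells: 15723 barcodes were shared in LV-Control, 15532 in LV-Aducanumab and 14799 in LV-⍺Aβ-Gas6, and UMI totals per shared barcode correlated across barcodes with r = 1.00 in each group. The tables of LV-Control and LV-Aducanumab, by contrast, shared 63 barcodes. Summed over genes, the runs of a group still differed more than counting noise allows, with a chi-square per degree of freedom of 13.9, 11.1 and 16.1, against 139 to 293 between groups. The tables of a group were therefore treated as 2 runs of 1 cell library, their mean was used, and each group counted as n = 1 cell library. How many animals a library held is not given in the sources used here.

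Gene names in the tables had hyphens replaced by dots. Of 32285 names, 28774 were found as written in the GENCODE annotation of build GRCm38, 2650 after restoring the hyphen, and 861 were kept as deposited. Gene positions come from that annotation.

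Barcodes present in both runs were kept with at least 500 UMIs, at least 300 genes and at most 10% mitochondrial counts. Doublets were scored per library against simulated doublets, and the top-scored 0.8% per 1000 barcodes were left out, which removed 1597, 1485 and 1451 barcodes in LV-Control, then LV-Aducanumab, then LV-⍺Aβ-Gas6. This left 12530, 12140 and 12017 cells, with median depths of 4899, 5986 and 6266 UMIs. All cells were clustered together without batch integration, from 2000 variable genes, 30 principal components, 20 neighbours and a Leiden resolution of 1, which gave 34 clusters. Clusters were named "X-like" from markers of 20 cell types fixed before the data were examined. A name needed its mean marker score to lead the next by 0.5 on the log2 scale and at least 3 markers detected in 10% of its cells, and a cluster of low UMI median also needed 1 of its own markers among its 10 leading genes. These margins were not part of the design fixed in advance. Clusters 11 and 16 stayed unnamed and held 9.78%, 5.11% and 5.86% of the kept cells of the 3 libraries.

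Genes were compared in 7 classes, which were picked by hand after the classes had been seen and without a written reason. The design asked for every class with at least 20 cells in every library. B-like, ependymal-like, erythroid-like, fibroblast-like and neutrophil-like cells also met that minimum, and their genes were not analysed here. Counts were summed per library and class, scaled with TMM factors (edgeR 4.0.16 in R 4.3.3) and expressed as CPM, counts scaled to library size. Folds are ratios of CPM. Their 95% intervals are exact conditional intervals of a ratio of Poisson counts, and intervals of cell shares are exact Clopper-Pearson intervals. These intervals cover counting error only, and say nothing about variation between animals or preparations. A fold against a count of 0 was computed against 3 UMIs over the group and is given as a lower bound.

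The design fixed before the data were examined used edgeR quasi-likelihood tests over 6 libraries, with camera and fry for gene lists, edgeR on cell numbers, and an interaction between classes. With 1 cell library per group none of these tests exists, so no p-value, standard error or adjusted value is given. The planned comparison of sums over all kept cells, and the interaction, were not analysed here. Counts of genes at least 1.5-fold different, with a mean of at least 20 CPM and the same direction in both runs, are a rule of size and not a test. The naming of genes was adapted after the single library per group had been found. Genes were named (a) by size, up to 10 higher and 10 lower in microglia-like cells and 3 and 3 in other classes, ordered by the log2 ratio with a pseudocount of 1 CPM, (b) from a list fixed in advance, and (c) as the 4 members furthest in the list's direction from each gene list standing apart from random lists. Genes named outside these rules are said to be chosen after their values were seen.

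The 22 gene lists were fixed before the data were examined. Clec7a, Mx1 and 1500015O10Rik were not analysed here. For each list, the median log2 ratio over members with at least 10 UMIs in a library was placed among the medians of 10000 random lists of the same size, matched on mean expression in 20 bins. This position describes these libraries and is not a test of the treatments. Steps in Python 3.11.15 used numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0, leidenalg 0.10.2 and matplotlib 3.10.9.

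The size rule was tested on simulated counts for LV-⍺Aβ-Gas6 against LV-Control microglia-like cells with 200 changed genes. All 50 genes changed 2-fold passed, 64% of those changed 1.5-fold passed, 88% of those changed 0.5-fold passed, and 0 of 5232 unchanged genes passed. The counts were Poisson draws from the LV-Control profile with the true scaling factor, so unchanged genes could differ by counting error only. The simulation therefore does not give the rule's false calls in real libraries. Between the real runs, 27, 18 and 31 genes differed at least 1.5-fold in LV-Control, then LV-Aducanumab, then LV-⍺Aβ-Gas6. A list of 15 genes changed 1.5-fold lay at percentile 100 of its random lists, and an unchanged list of 15 at percentile 80.6.

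Alternatives were RLE factors, no low-count filter, only the 2 groups compared, leaving out each run in turn, thinned sums, doublets kept, at least 1000 UMIs, at most 5% mitochondrial counts, a Leiden resolution of 0.5 and, for shares, TMM over classes or a denominator without microglia-like cells. CPM without scaling factors, and counts without X- and Y-linked genes, were added after the data had been seen.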

Results

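The data set profiled hippocampal cells of 5xFAD mice after injection of 1 of 3 vectors. LV-Control was the control vector, LV-Aducanumab encoded aducanumab, an antibody against aggregated amyloid-β, and LV-⍺Aβ-Gas6 encoded a fusion of an amyloid-β-binding part to Gas6, a ligand of the TAM receptors Axl and Mertk. Each group was represented by 1 cell library sequenced in 2 runs, with these UMI totals per run (99894926 and 96523322 in LV-Control, 106120023 and 107503393 in LV-Aducanumab, 111185342 and 108627941 in LV-⍺Aβ-Gas6). Every value below therefore stands for n = 1 library per group, without replicates, and its interval covers counting error only.

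The sex of the animals differed between libraries. Microglia-like cells of LV-Control held 0.10 CPM of Xist, the X-inactivation RNA of female cells, and 85.5 CPM of the Y-linked helicase gene Ddx3y. Xist stood at 1043 CPM in LV-Aducanumab and 1123 CPM in LV-⍺Aβ-Gas6, and Ddx3y at 0 UMIs in both. LV-Aducanumab and LV-⍺Aβ-Gas6 thus share a sex, so their direct comparison comes first. Sharing a sex does not make their animals alike. In endothelial-like cells, Trim12a stood at 0.624 CPM in LV-Aducanumab against 39.9 CPM in LV-⍺Aβ-Gas6, and in T-like cells at 0.448 against 55.0 CPM. Whether animals, preparation or vector account for this cannot be told apart with 1 library per group. Both comparisons with LV-Control differ in sex as well as in vector.

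Microglia-like cells were the largest class, with 6437 cells in LV-Control, 7872 in LV-Aducanumab and 7842 in LV-⍺Aβ-Gas6. Different clusters held them. Clusters 7, 8, 13 and 19, picked because at least 97% of their cells were from LV-Control, held 84% of the microglia-like cells of LV-Control. They held 0.445% and 0.905% of those of LV-Aducanumab and LV-⍺Aβ-Gas6, low shares that follow in part from the pick. Clusters 1, 2, 4, 5 and 12, picked for at most 5% LV-Control cells, held 4.07%, 90.3% and 77.8%. Clusters 8 and 4 both had Tmem119 and P2ry12 among their leading genes. LV-Aducanumab and LV-⍺Aβ-Gas6 were also spread unevenly over clusters 1, 2, 5, 6, 12 and 18, the last with interferon-induced genes such as Ifit2 and Ifi204 among its leading genes, so that differences between these 2 libraries mix the make-up of the class with levels per cell. Values within this class are therefore compared across cells that did not cluster together.

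The comparison of LV-⍺Aβ-Gas6 with LV-Aducanumab asks how microglia differ when an amyloid-β binder is coupled to a TAM ligand rather than given as an antibody that engages Fc receptors. Of 9 measured genes of MHC class II antigen presentation, 6 were at least 1.5-fold higher in LV-⍺Aβ-Gas6, led by H2-Eb1, at 874 CPM against 115 CPM (7.62-fold, 7.44 to 7.81). The interferon-induced T cell chemokine Cxcl9 stood at 52.1 CPM against 3.22 CPM, and Spp1 (osteopontin) and Gpnmb, which mark plaque-associated microglia, were 4.36-fold and 4.85-fold higher. Of the chemokine genes, Ccl3 was lower, at 1408 CPM against 3152 CPM, as was Ccl4, at 2371 CPM against 5100 CPM, while Ccl5 was 3.02-fold higher. The cytokine genes Il1b and Tnf were 1.74-fold (1.72 to 1.75) and 1.65-fold (1.63 to 1.68) lower.

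Of 5320 genes with at least 20 CPM on average, 111 were at least 1.5-fold higher in LV-⍺Aβ-Gas6 and 62 at least 1.5-fold lower, and 46 and 15 of them passed 2-fold. The MHC class II list had a median log2 ratio of 2.11, against -0.10 to 0.13 for the central 95% of random lists, and 6 of its 9 measured members passed the 1.5-fold rule upwards and 0 downwards. On chromosome 17, H2-Aa (34282744 to 34287823) stood at 1168 against 172 CPM and H2-Ab1 (34257689 to 34269419) at 949 against 167 CPM. Cd74, the invariant chain gene on chromosome 18 (60803848 to 60812652), stood at 3651 against 843 CPM, a 4.33-fold difference (4.29 to 4.37). The MHC class I list had a median of 0.71, with 8 of 17 members higher, among them H2-Q7 (2.27-fold), Tap1, a peptide transporter gene (2.05-fold), H2-D1 (1.90-fold) and the immunoproteasome gene Psmb9 (1.81-fold). All 8 lie on chromosome 17 between 25 and 50 Mb, as do H2-Aa, H2-Ab1, C4b and Tnf. A variant of that stretch, taken up below, thus bears on them as well. B2m, a member on chromosome 2, stood at 4495 against 3218 CPM. The interferon response list had a median of 0.95, with 15 of 26 measured members higher and 0 lower, including Ifi204 (3.30-fold), Gbp2 (3.23-fold) and Ifit3 (2.68-fold). MHC class II RNA was also higher in classes that make little of it: H2-Aa stood at 66.2 against 8.49 CPM in mural-like cells, and the list median was 1.30 in endothelial-like and 2.15 in astrocyte-like cells.

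The list of inflammatory cytokines and NF-kB targets had a median of -0.15, below its random lists, with 8 of 27 members lower and 3 higher. Cxcl9 is a member of the list, and the mean of the list was -0.0092. Cxcl1, a neutrophil chemokine gene, was 2.18-fold lower (2.07 to 2.29). Immediate early genes, which respond to tissue dissociation, had a median of -0.36, with 4 of 23 members lower and 1 higher, the lower ones being Egr1 at 191 against 415 CPM, Ier2 at 275 against 467 CPM, Fos at 504 against 807 CPM and Jund at 892 against 1388 CPM.

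The disease-associated microglia list had a median of 0.11, with 4 of 25 measured members higher and 2 lower. Itgax, an integrin gene of plaque-associated microglia, stood at 229 against 116 CPM and Fabp5, a lipid carrier gene, at 720 against 412 CPM. Apoe stood at 36203 against 28253 CPM, Cst7 at 1777 against 1416 CPM and Trem2, a lipid-sensing receptor gene, at 3746 against 3533 CPM (1.06-fold). The homeostatic list had a median of -0.13 with 0 of 15 members past 1.5-fold: Siglech stood at 429 against 624 CPM, Selplg at 723 against 836 CPM, Gpr34 at 864 against 984 CPM, P2ry12 at 774 against 926 CPM and Tmem119 at 421 against 372 CPM. With doublets kept, a setting in which cells were clustered again and a cluster of 1996 cells led by Gpnmb and Spp1 stayed unnamed, the medians of the disease-associated and homeostatic lists came to 0.0024 and -0.043, and neither list stood apart from its random lists. That cluster also had Ms4a7, H2-M2 and H2-Aa among its leading genes. It held 440, 277 and 1279 cells of LV-Control, then LV-Aducanumab, then LV-⍺Aβ-Gas6. In the main setting, cluster 6, also led by Gpnmb and Spp1, was counted as microglia-like, with border-associated macrophage as its second score. With doublets kept, and the unnamed cluster thus outside the microglia-like class, the MHC class II median still stood above its random lists. How much of the MHC class II difference cluster 6 carries in the main setting was not tested. Of the complement list (median 0.16), C3 was 3.13-fold and C4b 2.38-fold higher, while Itgam was 1.38-fold and C1qa 1.15-fold higher.

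Gas6 itself, on chromosome 8 (13465374 to 13494490), stood at 91.7 CPM in LV-⍺Aβ-Gas6, 78.1 CPM in LV-Aducanumab and 77.5 CPM in LV-Control. The tables do not say whether RNA of the fusion was counted in this gene. Axl stood at 136 against 94.8 CPM (1.43-fold, 1.39 to 1.48) and Mertk at 222 against 219 CPM. The list of TAM receptors, ligands and efferocytosis genes had a median of 0.0086, inside its random lists, with members on both sides: Tgm2 was 2.58-fold higher and Socs3 1.55-fold lower, both chosen after their values were seen. Fc gamma receptor signalling (-0.028), lysosome (0.020) and cholesterol synthesis (0.045) lay inside theirs as well.

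Glycolysis genes had a median of 0.14 with 0 members past 1.5-fold, Gpi1 being 1.23-fold, Pgk1 1.18-fold, Aldoa 1.17-fold and Pkm 1.14-fold higher. Cell cycle genes had a median of 0.41, but only 4 of 20 members reached 20 CPM: Mcm3 stood at 27.3 against 19.4 CPM, Stmn1 at 23.2 against 22.1, Hmgb2 at 116 against 118 and Pcna at 61.2 against 67.9. Lists made for other cells were read in microglia-like cells as well. T cell activation had a median of 0.19, with Ccl5 3.02-fold and Lag3 1.41-fold higher. Endothelial activation had a median of -0.36, but only 5 of 16 measured members reached 20 CPM: Il6st was 1.54-fold and Icam1 1.08-fold lower, and Tjp1 was 1.14-fold and Vcam1, chosen after its values were seen, 2.74-fold higher. Reactive astrocyte (0.0047, 7 members higher and 1 lower) and disease-associated oligodendrocyte (0.018, 3 higher and 0 lower) genes lay inside their random lists, as did neuronal RNA (0.010), myelin RNA (0.059) and the sex-linked genes (0.0049). Haemoglobin RNA had a median of -1.28.

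Among the 10 genes furthest upwards by size, those outside the lists were the immunoglobulin gene Ighg2c (23.2 against 1.32 CPM), the neuropeptide gene Cck (42.4 against 7.38 CPM) and the galectin gene Lgals1 (189 against 49.0 CPM). Among the 10 furthest downwards were the survival gene Bcl2a1d (4.65-fold), the creatine synthesis gene Gatm (4.29-fold), the ribosomal gene Rpl29 (3.34-fold), Ighg2b (2.92-fold), Chst2 (2.33-fold) and the antiviral deaminase gene Apobec3 (2.30-fold). Immunoglobulin transcripts are products of plasma cells, and Ighg2c was also 17.3-fold higher in endothelial-like and 13.9-fold in mural-like cells. Rpl29 was 3.17-fold lower in mural-like cells too. Reads can be shared between Ighg2b and Ighg2c, between Bcl2a1d and its paralogs, among H2 class I genes, and between Rpl29 and its pseudogenes, so their values are uncertain.

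**Figure D1:**
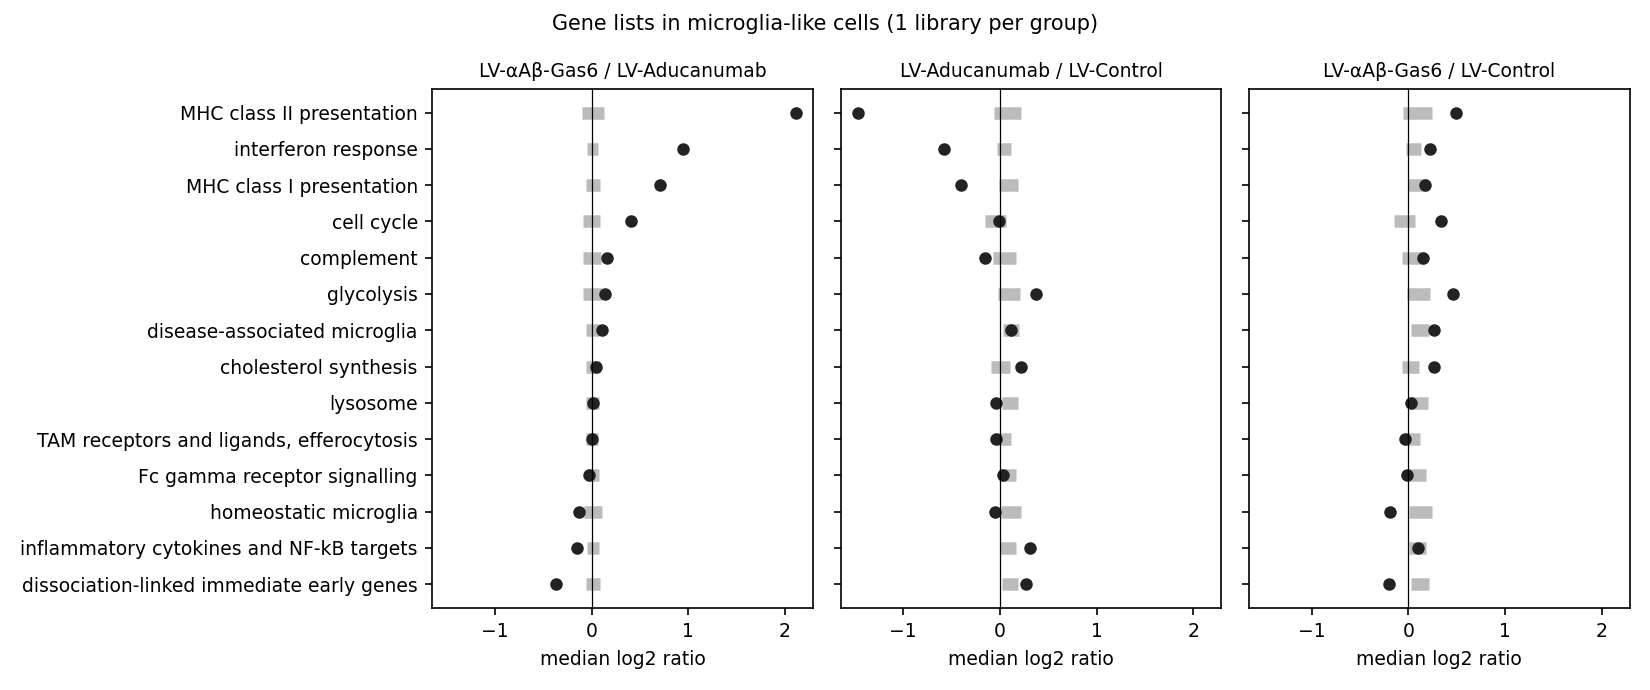
Median log2 ratio of gene lists in microglia-like cells (points) and the central 95% of 10000 random lists (grey bars) for the 3 comparisons, from 1 library per group. MHC class II lies at 2.11 in LV-⍺Aβ-Gas6 over LV-Aducanumab, -1.47 in LV-Aducanumab over LV-Control and 0.49 in LV-⍺Aβ-Gas6 over LV-Control.

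**Figure D2:**
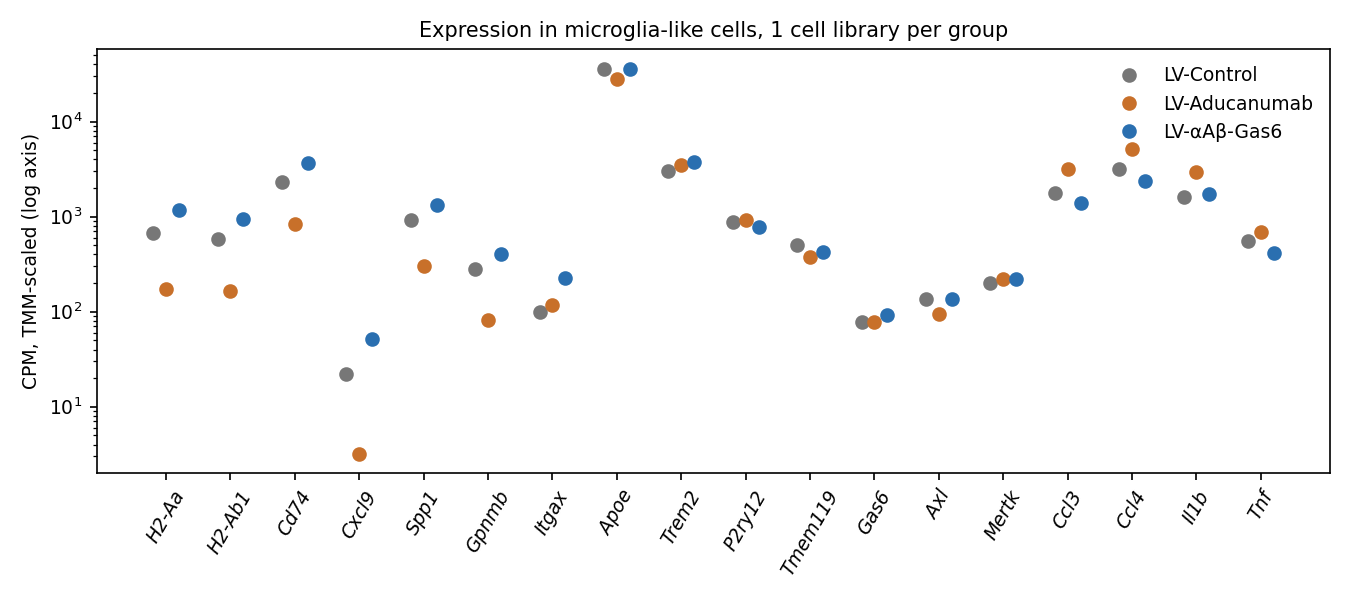
CPM (log axis) of 18 genes in microglia-like cells of the 3 libraries, chosen for the plot from the gene lists, each point 1 library. Cd74 lies at 2335, 843 and 3651 CPM, and Ccl3 at 1793, 3152 and 1408 CPM, in LV-Control, then LV-Aducanumab, then LV-⍺Aβ-Gas6.

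The comparison of LV-Aducanumab with LV-Control asks what expression of the antibody does to the cells of the amyloid-bearing hippocampus. In microglia-like cells, 5 of 9 MHC class II and 10 of 26 interferon genes were at least 1.5-fold lower in LV-Aducanumab and 0 higher, with H2-Eb1 at 115 against 540 CPM and the interferon-induced GTPase gene Gbp2 at 9.80 against 23.5 CPM. Of 27 inflammatory genes, 9 were higher and 4 lower, with Il1b at 2976 against 1610 CPM, Ccl3 at 3152 against 1793 CPM and the inflammasome sensor gene Nlrp3 at 255 against 138 CPM. Spp1 was lower, at 305 against 922 CPM.

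In all, 120 genes were at least 1.5-fold higher and 107 lower, and 24 and 42 passed 2-fold. Without scaling factors the split was 79 higher and 139 lower. The MHC class II list had a median of -1.47 with 5 of 9 members lower, H2-Aa by 3.91-fold, H2-Ab1 by 3.48-fold and Cd74 by 2.77-fold (2.74 to 2.80). MHC class I had a median of -0.40 with 5 of 17 members lower, among them H2-Q7 (1.79-fold), H2-D1 (1.70-fold), Tap1 (1.69-fold) and H2-T23 (1.56-fold). The named ones lie on chromosome 17 between 25 and 50 Mb. The interferon list had a median of -0.58 with 10 of 26 members lower, including Ifi204 (7.88-fold), Gbp2 (2.40-fold) and the nucleic acid sensor gene Zbp1 (2.17-fold). Of these, Ifi204 lies in a bin of chromosome 1 taken up below. The inflammatory list had a median of 0.31 and a mean of 0.11. Of its members, Cxcl1 was 2.59-fold higher, and Ccl4 and Tnf were 1.61-fold and 1.23-fold higher. Immediate early genes had a median of 0.27, with 2 of 23 members higher and 2 lower: Ier3 was 1.94-fold, Fos 1.60-fold, Atf3 1.46-fold and Ier2 1.43-fold higher.

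The complement list had a median of -0.15, with C4b 3.26-fold and C3 2.61-fold lower. The disease-associated list (0.12) lay inside its random lists, but outside them with doublets kept (0.21), and the homeostatic list (-0.049) below them, with Olfml3 at 642 against 897 CPM, Tmem119 at 372 against 505 CPM, Siglech at 624 against 739 CPM and Sparc at 1815 against 2091 CPM. The homeostatic gene P2ry12 went the other way, 1.05-fold higher. Of the disease-associated genes fixed in advance, Apoe was 1.26-fold lower, while Trem2, Cst7 and Itgax were 1.17-fold, 1.12-fold and 1.18-fold higher. Lysosome genes had a median of -0.040, with Ctsc, Ctss and Psap 1.28-fold, 1.25-fold and 1.24-fold lower. Glycolysis genes had a median of 0.37, with the glucose transporter gene Slc2a1 at 207 against 119 CPM, Pfkl at 117 against 82.9 CPM and Ldha at 327 against 247 CPM. Cholesterol synthesis had a median of 0.22, with Srebf2, a transcription factor gene of sterol synthesis, at 44.9 against 33.6 CPM. Gas6 differed by 1.01-fold (0.966 to 1.05). Axl was 1.44-fold lower, and Mertk 1.10-fold higher. The TAM list had a median of -0.041 at the lower edge of its random range (-0.041 to 0.12), and Mfge8, a phosphatidylserine bridging protein gene, was 1.51-fold lower. With doublets kept, both turned direction, to a median of 0.0018 and to 1.08-fold higher.

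By size, the higher genes were Xist, Tsix, the interferon-inducible gene Ifi202b (0 UMIs in LV-Control, at least 289-fold higher), the aspartic protease gene Ctse (12.6-fold, 11.5 to 13.8), Pttg1 (5.27-fold), G0s2 (4.64-fold), Bcl2a1d (4.31-fold), Rpl29 (4.22-fold), Igsf8 (3.41-fold) and Rab7b (3.29-fold). Lower were Ddx3y (at least 1762-fold), the macrophage gene Ms4a7 (29.8-fold), Ifi204, Cxcl9 (6.80-fold), the B cell chemokine gene Cxcl13 (5.27-fold), H2-Eb1 and the immunoglobulin genes Ighg2c (63.8-fold), Igha (19.8-fold), Jchain (18.4-fold) and Igkc (6.95-fold). B-like cells made up 0.288% of LV-Aducanumab and 1.48% of LV-Control cells, and Igkc was also lower in endothelial-like cells, at 87.5 against 647 CPM. The haemoglobin list had a median of 0.70. Reactive astrocyte and disease-associated oligodendrocyte genes had medians of -0.15 and -0.16, with Cp, the ceruloplasmin gene, 4.75-fold and Vim 1.79-fold lower.

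The comparison of LV-⍺Aβ-Gas6 with LV-Control asks the same of the fusion. Here 4 of 9 MHC class II genes were at least 1.5-fold higher, with Cd74 at 3651 against 2335 CPM (1.56-fold, 1.55 to 1.57) and H2-Aa at 1168 against 675 CPM. Of 25 disease-associated genes, 4 were higher, led by the lipase gene Lpl at 453 against 180 CPM and Itgax at 229 against 98.4 CPM, and 1 was lower, Ch25h (1.58-fold, chosen after its value was seen). Of the inflammatory genes, Il1b differed by 1.06-fold (1.05 to 1.07), while Tnf, Ccl3 and Ccl4 were 1.34-fold, 1.27-fold and 1.33-fold lower.

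In all, 116 genes were at least 1.5-fold higher and 59 lower, and 28 and 21 passed 2-fold. Without scaling factors the split was 75 and 85, which shifted the median log2 ratio of all genes by -0.10. With doublets kept, 74 genes were higher. The MHC class II list had a median of 0.49 with 4 of 9 members higher, H2-Ab1 and H2-Eb1 by 1.63-fold and 1.62-fold. The interferon list had a median of 0.23 with 2 of 26 higher, Ifit3 (1.73-fold) and Ifit2 (1.55-fold), and 1 lower, Ifi204, at 33.5 against 80.0 CPM. Isg15 and Ifi27l2a were 1.38-fold and 1.34-fold higher. MHC class I (0.17) and the inflammatory list (0.097) lay inside their random lists, the former not with doublets kept (0.18).

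The disease-associated list had a median of 0.27 with 4 of 25 members higher, including the growth factor gene Csf1 (1.75-fold) and Fabp5 (1.70-fold), while Cst7 and Spp1 were 1.41-fold and 1.44-fold higher and Apoe differed by 1.02-fold. Homeostatic genes had a median of -0.19, with Siglech 1.72-fold lower (1.70 to 1.75) and Olfml3, Csf1r, Tmem119 and P2ry12 lower by 1.25-fold, 1.20-fold, 1.20-fold and 1.14-fold. Glycolysis had a median of 0.46 with 3 of 13 members higher: Slc2a1 by 1.69-fold, Pgk1 by 1.55-fold and Pfkl at 125 against 82.9 CPM. Cholesterol synthesis had a median of 0.27, with Cyp51 1.47-fold and Hmgcs1 1.42-fold higher. Fc gamma receptor signalling had a median of -0.013, below its random range (0.0058 to 0.18), with the signalling chain gene Fcer1g 1.47-fold lower and Fcgr2b 1.25-fold lower. Both genes lie on chromosome 1 between 150 and 175 Mb, a bin taken up below. The Fc gamma receptor median turned positive without LV-⍺Aβ-Gas6 replicate 1 (0.0074) and with doublets kept (0.020). The TAM list had a median of -0.034, at the edge of its range, with 1 of 28 members higher and 1 lower. Socs3, Elmo1 and Pros1 were 1.38-fold, 1.27-fold and 1.21-fold lower and Mfge8 stood at 35.7 against 53.6 CPM, while Tgm2, a transglutaminase gene chosen after its values were seen, was 2.04-fold higher. With doublets kept, this median turned to 0.0034. Axl differed by 1.00-fold and Mertk was 1.12-fold higher. Immediate early genes had a median of -0.20, with Egr1 at 191 against 304 CPM, Klf2 at 74.1 against 109 CPM and Jun at 1256 against 1686 CPM. Haemoglobin RNA had a median of -0.68 and neuronal RNA one of -0.28, the latter inside its random lists with doublets kept (-0.19). Cell cycle genes had a median of 0.34, again with 4 of 20 members at 20 CPM, of which Stmn1 was 1.58-fold higher.

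By size, the higher genes were Xist, Tsix, Ifi202b (at least 780-fold), Ctse (11.8-fold), Pttg1 (5.73-fold), Rab7b (4.28-fold), Gas7 (3.60-fold), Igsf8 (3.22-fold), Npl (3.17-fold) and Slamf8 (3.09-fold). Lower were Ddx3y (at least 1899-fold), Igha (7.55-fold), Ms4a7 (6.23-fold), Ighg2b (5.98-fold), Gatm (5.48-fold), Jchain (5.00-fold), Enpp2 (3.78-fold), Cd72 (3.78-fold), Ighg2c (3.62-fold) and Pdlim4 (3.44-fold). Enpp2 is abundant in choroid plexus, whose share was lower in LV-⍺Aβ-Gas6.

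Shares of cells were compared next, with the question of which cell classes differed in number. T-like cells made up 7.55% of LV-⍺Aβ-Gas6 cells (907 cells, 7.08% to 8.03%), 2.28% of LV-Aducanumab cells (277 cells, 2.02% to 2.56%) and 3.22% of LV-Control cells (404 cells, 2.92% to 3.55%), so that the share in LV-⍺Aβ-Gas6 was 3.31-fold that in LV-Aducanumab (2.89 to 3.80). Microglia-like cells made up 51.4%, 64.8% and 65.3% of LV-Control, then LV-Aducanumab, then LV-⍺Aβ-Gas6. Endothelial-like cells made up 15.3%, 12.1% and 9.06%, and mural-like cells 8.19%, 7.24% and 5.68%. Choroid plexus-like epithelium made up 3.70% of LV-Control against 0.651% and 0.682%, a class that lines the ventricles next to the hippocampus. B-like cells made up 1.48%, 0.288% and 0.924%, astrocyte-like cells 3.34%, 4.09% and 2.75%, border-associated macrophage-like cells 1.28%, 0.931% and 0.799%, ependymal-like cells 1.13%, 0.486% and 0.383%, and erythroid-like cells 0.431%, 0.997% and 0.366%. The B-like class joined cluster 24, led by immunoglobulin genes (157, 21 and 50 cells), and cluster 28, led by Cd79a (28, 14 and 61 cells). Against LV-Control, LV-⍺Aβ-Gas6 thus had fewer cells of the former and more of the latter. Shares sum to a whole, and the minimum of 500 UMIs and the median depths of 4899, 5986 and 6266 UMIs bear on them. Among cells other than microglia-like cells, T-like cells of LV-⍺Aβ-Gas6 stood at 3.28-fold the share in LV-Control, against 2.34-fold among all cells. With this denominator, LV-Aducanumab over LV-Control turned direction for endothelial-like (1.09-fold), mural-like (1.22-fold) and border-associated macrophage-like cells (1.01-fold), and LV-⍺Aβ-Gas6 over LV-Control for astrocyte-like cells (1.16-fold). The unnamed cluster 11, with Gfap, Aldoc and Slc1a2 among its leading genes, held 9.61%, 1.13% and 1.36% of all cells. Counted as astrocyte-like, it would give LV-Control the largest share of that class, so no direction is read from the astrocyte-like shares against LV-Control.

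**Figure D3:**
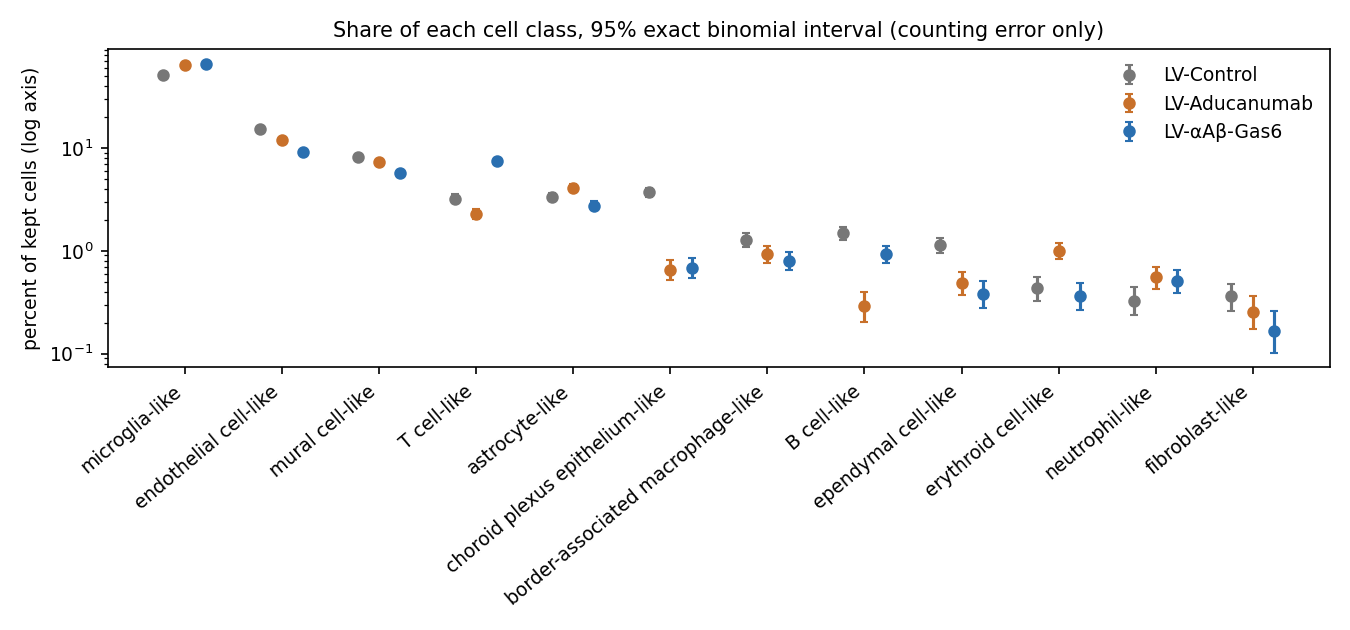
Percent of kept cells (log axis) in each class for the 3 libraries, with 95% exact binomial intervals that cover counting error only. T-like cells lie at 3.22%, 2.28% and 7.55% in LV-Control, then LV-Aducanumab, then LV-⍺Aβ-Gas6.

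Other classes, picked after the classes had been seen, were compared by the same rule of size. That rule was simulated for microglia-like cells only. In classes with few UMIs per gene, counting error alone can bring genes past 1.5-fold, so counts of genes are not compared between classes. In endothelial-like cells, 3 of the genes named by size were higher in LV-Aducanumab than in both other libraries: the iron-binding lipocalin gene Lcn2 stood at 149 CPM against 7.39 CPM in LV-Control and 7.59 CPM in LV-⍺Aβ-Gas6, Gsta4 at 266 against 42.8 and 35.5 CPM, and Scgb3a1 at 207 CPM against 20.6 CPM in LV-⍺Aβ-Gas6. The endothelial activation and barrier list had a median of 0.40 in LV-Aducanumab over LV-Control and -0.29 in LV-⍺Aβ-Gas6 over LV-Aducanumab, with 6 of 18 members higher and 1 lower, and 1 higher and 6 lower, respectively. The leukocyte adhesion gene Icam1 (226, 74.8 and 99.3 CPM in LV-Aducanumab, LV-Control and LV-⍺Aβ-Gas6) and the venular chemokine receptor gene Ackr1 (86.2, 7.39 and 16.8 CPM) were members chosen after their values were seen. Haemoglobin RNA was on the same side, with medians of 1.47 and -1.54, and erythroid-like cells had 2.31-fold the share in LV-Aducanumab over LV-Control. Scgb3a1 was among the leading genes of the erythroid-like cluster, and Lcn2 among those of the neutrophil-like cluster. The erythroid-like cluster also scored high for endothelial markers (5.65, against 8.23 for erythroid markers), so Scgb3a1 there is not tied to blood cells. Immediate early genes had medians of 0.61 in LV-Aducanumab and 0.53 in LV-⍺Aβ-Gas6 over LV-Control. The neutrophil gene S100a9, also among the leading genes of the neutrophil-like cluster, stood at 74.3 CPM in LV-⍺Aβ-Gas6 and was 49.6-fold and 18.9-fold lower in LV-Aducanumab and LV-Control. Counts of genes at least 1.5-fold different were 104 higher and 83 lower in LV-⍺Aβ-Gas6 over LV-Aducanumab, 147 and 115 in LV-Aducanumab over LV-Control, and 118 and 56 in LV-⍺Aβ-Gas6 over LV-Control.

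In T-like cells, the cytokine gene Il17a stood at 67.2 and 82.3 CPM in LV-Aducanumab and LV-⍺Aβ-Gas6 (75 and 268 UMIs) against 0.70 CPM in LV-Control (1 UMI), and Il13, a type 2 cytokine gene, at 101 CPM in LV-Control (144 UMIs) against 0.45 and 0.61 CPM. Cell cycle genes were highest in LV-Aducanumab, with a median of 1.23 over LV-Control, and -0.97 for LV-⍺Aβ-Gas6 over LV-Aducanumab, where the histone gene Hist1h1b was 5.06-fold lower. Only 7 of the list's 18 measured members reached 20 CPM, 4 were at least 1.5-fold higher in the first comparison and 3 lower in the second, and LV-Aducanumab had 277 T-like cells. T cell activation genes had a median of 0.32 in LV-⍺Aβ-Gas6 over LV-Aducanumab, with 5 of 19 members higher and 0 lower. Lists made for other cells stood further from 0 in the same comparison: MHC class II at 1.29, homeostatic microglia genes at -0.58, and haemoglobin RNA, with 3 of 4 measured members higher. Genes at least 1.5-fold different were 288 higher and 157 lower in LV-⍺Aβ-Gas6 over LV-Aducanumab, 210 and 268 in LV-Aducanumab over LV-Control, and 279 and 210 in LV-⍺Aβ-Gas6 over LV-Control. The immunoglobulin gene Ighg1 stood at 357 against 10.3 CPM in LV-⍺Aβ-Gas6 and LV-Aducanumab T-like cells, RNA that T cells do not make.

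In astrocyte-like cells, cholesterol synthesis genes were lower in LV-Aducanumab: 15 of 18 were at least 1.5-fold higher and 1 lower in LV-⍺Aβ-Gas6 over LV-Aducanumab (median 0.79), and 10 lower and 1 higher in LV-Aducanumab over LV-Control (median -0.71). Of all 7408 genes at the minimum in this class, 416 were higher and 400 lower in the first of these comparisons, and 376 and 402 in the second. Haemoglobin RNA had medians of -1.78 and 0.85. Immediate early genes, which respond to tissue dissociation, also lay below their random lists in the first comparison. Hmgcs1, an early enzyme gene of the pathway chosen after its values were seen, stood at 144, 56.3 and 182 CPM in LV-Control, then LV-Aducanumab, then LV-⍺Aβ-Gas6. The cytokine signalling suppressor gene Socs3 was 4.04-fold lower in LV-⍺Aβ-Gas6 than in LV-Aducanumab (2.44 to 7.65). Disease-associated microglia genes had a median of 0.48 in LV-⍺Aβ-Gas6 over LV-Aducanumab in this class, in which microglial RNA is foreign.

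Border-associated macrophage-like cells, of which there were 160, 113 and 96, held H2-M2, a class I-like gene, at 196 CPM in LV-Control, 0 UMIs in LV-Aducanumab and 358 CPM in LV-⍺Aβ-Gas6. Of 5609 genes at the minimum in this class, 648 were higher and 602 lower in LV-⍺Aβ-Gas6 over LV-Aducanumab. With so few cells, counting error alone can bring genes past the rule, and both runs read the same cells. The hyaluronan receptor gene Lyve1 stood at 151, 143 and 1.93 CPM, and Cxcl1 at 59.6, 160 and 8.70 CPM. The chemokine gene Ccl22 stood at 67.7 CPM in LV-⍺Aβ-Gas6 (35 UMIs) and at 0 UMIs in LV-Aducanumab. In mural-like cells, 71 genes were higher and 51 lower in LV-⍺Aβ-Gas6 over LV-Aducanumab, and the named genes were Ighg2c, H2-Aa and H2-Eb1 (higher) and Ighg2b, Rpl29 and the haemoglobin gene Hbb-bs (lower). In choroid plexus-like epithelium, with 79 and 82 cells in LV-Aducanumab and LV-⍺Aβ-Gas6, the stress-responsive matrix gene Ccn1 was 5.12-fold higher (2.48 to 10.5) and Cxcl2 7.93-fold lower (4.26 to 18.4) in LV-⍺Aβ-Gas6. With at most 5% mitochondrial counts, Cxcl2 turned direction, to 1.23-fold higher. Among the 5045 genes at the minimum in choroid plexus-like epithelium, 570 were higher and 482 lower in LV-⍺Aβ-Gas6 over LV-Aducanumab, with the same limit of few cells.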

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

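All tests in this part were chosen after the results they address had been seen. An unnamed cluster, number 16, held 3.98% of LV-Aducanumab cells and 4.49% of LV-⍺Aβ-Gas6 cells against 0.168% of LV-Control cells, a signal outside the named classes and above the control. Its cells had a median of 952 UMIs, and Xist and Tsix were among its leading genes. Whether sex, vector or preparation accounts for it was not tested. Cluster 11, also unnamed, with a median of 908 UMIs and with the astrocyte genes Gfap, Aldoc and Slc1a2 among its leading genes, held 9.61% of LV-Control, 1.13% of LV-Aducanumab and 1.36% of LV-⍺Aβ-Gas6 cells.

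MHC class II genes were higher in microglia-like cells of LV-⍺Aβ-Gas6 than of LV-Aducanumab. RNA of the B-like class as a whole, or of border-associated macrophage-like cells, was argued against, while other sources were not tested. Summed B cell markers reached 0.980% of the level that B-like RNA would bring if it carried the excess, and border-associated macrophage markers 7.96%. The B cell markers include Jchain and Iglc2, leading genes of cluster 24, so RNA of cluster 28 alone was not tested. A variant of the H2 region on chromosome 17 does not reach Cd74 on chromosome 18, whose fold had a lower bound of 4.29, whereas for the H2 genes themselves a variant cannot be told apart from a response, since 3 of the 7 measured ones lay above Cd74. The 8 MHC class I genes past 1.5-fold, C4b and Tnf lie in the same 25 Mb bin, so a variant cannot be set aside for them either. H2-M2 and BC004004 lie there too. H2-M2 stood at 0 UMIs in LV-Aducanumab and 358 CPM in LV-⍺Aβ-Gas6 in border-associated macrophage-like cells. BC004004 was lower in LV-Aducanumab in both microglia-like and mural-like cells. Both would go with a variant of the segment, which was not tested further. More interferon gamma from T-like cells is a candidate explanation: Ifng was 2.47-fold higher in all kept cells of LV-⍺Aβ-Gas6 than of LV-Aducanumab, with a lower bound of 2.08. It stood at 5.39 CPM in LV-⍺Aβ-Gas6, 2.18 CPM in LV-Aducanumab and 4.68 CPM in LV-Control. The T-like share was itself 3.31-fold higher, so the Ifng fold adds little beyond that share. Within T-like cells, Ifng was lower in LV-⍺Aβ-Gas6 than in LV-Aducanumab (126 against 146 CPM), and LV-Control T-like cells held more of it (221 CPM). Differences between animals or preparations stay open, as each group was 1 library.

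Ccl3, Ccl4, Il1b and Tnf were lower in microglia-like cells of LV-⍺Aβ-Gas6 than of LV-Aducanumab, and immediate early genes were lower with them. If a weaker response to dissociation were the cause, immediate early genes would be lower in other classes too. They lay below their random lists in 2 of 3 other classes, endothelial-like (median -0.051) and astrocyte-like (-0.29) but not mural-like cells. Handling and treatment therefore cannot be told apart here, because each suspension was prepared once and the classes disagree.

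Genes differed between LV-Control and both other libraries, which differ in sex. X- and Y-linked genes made up at most 4.57% of the differing genes in either comparison, so they were not themselves the bulk of these genes. Of the 5320 genes compared, however, 5122 lay on autosomes, so few X- or Y-linked genes were there to differ. Their low share therefore does not tell how much of the pattern goes with sex, and effects of sex on autosomal genes stay open. Haplotypes of the mixed B6/SJL background were tested as well: the share of differing genes in the fullest 25 Mb bin, chromosome 1 from 150 to 175 Mb, was 15.5% and 16.7% in the 2 comparisons, inside the central 95% of random gene sets (up to 20.6% and 17.9%). By the bound written for it, that value would have counted against haplotypes, but bins with few measured genes set the random range and a segment too small to fill a bin is not forbidden. A second statistic, tried because the first had not separated them, scaled the excess per bin. It gave 5.03 and 6.81 for the same bin, above the central 95% of random sets (up to 4.35 and 4.65). In the first comparison, 4 of 1000 sets were as high. The H2 bin, however, did the same between the 2 treated libraries (6.55), where variant and response are themselves open. The cause of such a bin was therefore left open. The named genes Npl, Igsf8, Slamf8, Ifi204 and Ifi202b lie in the chromosome 1 bin, as do Fcer1g and Fcgr2b. For these genes, haplotype, sex and vector cannot be told apart.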

How the results depend on the processing

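CPM without scaling factors, counts without X- and Y-linked genes and the wording of the rule for list medians were chosen after the data had been seen. No paired analysis was possible because the replicates of a group were runs of 1 cell library and no result came from a test. DESeq2, the replicate block, camera with an estimated correlation and fry were not run for the same reason. A list median counted as kept when it stayed on its side of, or inside, the central 95% of random lists. Counts of genes stayed within 1.5 times of the main count in 87 comparisons with an alternative and left that range in 9. For folds of named genes, 4048 values under an alternative stayed inside the counting interval of the main fold. Another 480 values, from 184 named folds, left that interval, and 2 values turned the direction of a fold of at least 1.5. MHC class II and interferon medians in microglia-like cells kept their side under every alternative run. With sums thinned to the smallest total, no count of genes left its range, while in LV-⍺Aβ-Gas6 over LV-Control the T cell activation median (0.077) left the range of its random lists and the neuronal RNA median (-0.25) entered it. With doublets kept, cells were clustered again: a cluster of 1996 cells led by Gpnmb and Spp1 stayed unnamed, and a cluster of 868 led by Tsix was named astrocyte-like. The cause of the following shifts was not tested, except that dropping the low-count filter admits genes with a few UMIs.

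With no low-count filter, 2182 genes were higher and 2844 lower in LV-⍺Aβ-Gas6 over LV-Aducanumab, 1821 and 3407 in LV-Aducanumab over LV-Control, and 1744 and 3707 in LV-⍺Aβ-Gas6 over LV-Control. Without scaling factors, 79 (main value 120) and 75 (116) were higher in the comparisons with LV-Control. With doublets kept, 74 were higher in LV-⍺Aβ-Gas6 over LV-Control.

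The TAM list median in LV-Aducanumab over LV-Control (-0.041) became -0.033 with RLE factors, 0.0018 with doublets kept and -0.056 to -0.029 with 1 run left out. In LV-⍺Aβ-Gas6 over LV-Control (-0.034) it became 0.0034 with doublets kept, -0.033 with at most 5% mitochondrial counts, -0.029 at a Leiden resolution of 0.5 and -0.049 to -0.0018 with 1 run left out. The Fc gamma receptor median in LV-⍺Aβ-Gas6 over LV-Control (-0.013) became 0.020 with doublets kept and -0.013 to 0.0074 with 1 run left out, the positive value coming without LV-⍺Aβ-Gas6 replicate 1. With doublets kept, the homeostatic and disease-associated medians in LV-⍺Aβ-Gas6 over LV-Aducanumab entered their random ranges (-0.043 and 0.0024), the disease-associated median in LV-Aducanumab over LV-Control left its random range (0.21), as did the MHC class I median in LV-⍺Aβ-Gas6 over LV-Control (0.18), and Mfge8 in LV-Aducanumab over LV-Control turned to 1.08-fold higher. With at most 5% mitochondrial counts, Cxcl2 in choroid plexus-like epithelium, LV-⍺Aβ-Gas6 over LV-Aducanumab, turned to 1.23-fold higher.

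For shares in LV-Aducanumab over LV-Control, the microglia-like fold (1.26) was 1.08 with TMM over classes, 1.31 with doublets kept, 1.19 with at least 1000 UMIs and 1.21 at a Leiden resolution of 0.5. In LV-⍺Aβ-Gas6 over LV-Control (1.27) it was 1.12 with TMM over classes, 1.19 with doublets kept, 1.21 with at least 1000 UMIs, 1.22 with at most 5% mitochondrial counts and 1.21 at a Leiden resolution of 0.5, and in LV-⍺Aβ-Gas6 over LV-Aducanumab 0.909 with doublets kept. The T-like fold in LV-⍺Aβ-Gas6 over LV-Control (2.34) was 2.05 with TMM over classes. Among cells other than microglia-like cells it was 3.28, and in LV-Aducanumab over LV-Control (0.708) it was 0.979. With that denominator, endothelial-like (1.09), mural-like (1.22) and border-associated macrophage-like (1.01) cells in LV-Aducanumab over LV-Control and astrocyte-like cells in LV-⍺Aβ-Gas6 over LV-Control (1.16) turned direction, the last also with doublets kept (1.63).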

Other observations

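Some genes differed by library in classes of different origin, and were chosen after their values were seen. Trim12a, a gene of the TRIM family of antiviral proteins, stood at 26.7, 0.218 and 28.1 CPM in microglia-like cells of LV-Control, then LV-Aducanumab, then LV-⍺Aβ-Gas6, at 32.4, 0.624 and 39.9 CPM in endothelial-like cells and at 53.8, 0.448 and 55.0 CPM in T-like cells. BC004004 stood at 179, 55.0 and 202 CPM in microglia-like cells and at 118, 38.1 and 129 CPM in mural-like cells. The ribosomal gene Rpl26 stood at 1245, 3033 and 3146 CPM in microglia-like cells and at 701, 1691 and 1663 CPM in endothelial-like cells. Pttg1, a regulator of chromosome separation, stood at 5.76, 124 and 122 CPM in endothelial-like and 1.18, 96.5 and 89.3 CPM in choroid plexus-like cells.

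Transcripts of secretory cells were found in classes that do not make them. Ttr, the transthyretin gene of choroid plexus epithelium, stood at 1967, 669 and 616 CPM in microglia-like cells of LV-Control, then LV-Aducanumab, then LV-⍺Aβ-Gas6, and at 2921, 851 and 808 CPM in endothelial-like cells, in the order of the choroid plexus-like shares of LV-Control against the other libraries. Igkc stood at 447, 64.3 and 169 CPM in microglia-like cells and at 958, 102 and 264 CPM in mural-like cells.

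Neutrophil-like cells made up 0.327% (0.235% to 0.444%), 0.552% (0.428% to 0.700%) and 0.508% (0.389% to 0.652%) of LV-Control, then LV-Aducanumab, then LV-⍺Aβ-Gas6, and fibroblast-like cells 0.359%, 0.255% and 0.166%. In T-like cells, Cd4 stood at 63.9, 77.0 and 163 CPM, Cd8a at 364, 362 and 262 CPM, and the granzyme gene Gzmb at 122, 64.9 and 46.2 CPM, genes chosen after their values were seen.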
